A study of Mus musculus with 2 samples.

How the data were processed

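Bone marrow neutrophils of 1 group labelled Jdp2 knockout and 1 labelled wild type were each measured on 1 Affymetrix array after biotin labelling of total RNA, per the labels' protocols, which also give the mice a mixed strain background. Whether an array held RNA of 1 mouse or of several is not given in the sources used here. The deposited values are probe set summaries on a log2 scale made with RMA, per the submitters' processing notes. Its version, background step and normalisation step are not given in the sources used here. The sorted values of the 2 arrays differed by at most 0.117, so the authors' values had already been brought to nearly the same distribution. RMA summaries carry no detection call, and weak values hold background as well as signal, which understates the fold of weak genes and adds noise to them.

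The table held 45101 probe sets, of which 64 were control probe sets and were used only for quality values. Genes were named through the platform annotation that pairs probe sets with symbols, and symbols were updated through their Entrez identifiers against a gene table of assembly GRCm38.p6. Of the other 45037 probe sets, 34945 had 1 gene symbol, 932 had several and were not named, and 9160 were not listed in the annotation and stayed unnamed. Of the 34945, 34741 matched the gene table by identifier and 204 kept the symbol of the annotation. Both columns of values were mapped to a sample. The files name no genome build, so no coordinates are printed, and the gene table was used only for names and for the order of neighbouring genes.

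Each of 18193 genes was represented by its probe set with the highest mean over both arrays. A gene passed the level filter when the higher of its 2 values was at or above the median of the 45037 probe sets on that array, which left 11168 genes. With 1 array per group no test between groups is possible, and genes were counted by a fixed size rule, a log2 difference of at least 1 in either direction, which is 2-fold. The median difference of the genes that passed was -0.04. Where the lower value of a named gene lay under its array's median, a fold was also computed with that value raised to the median. Technical spread was the SD of the difference over the passing probe sets of a gene. It reflects probe sets on shared RNA and says nothing of spread between mice.

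Gene lists were written before the data were examined. They were the AP-1 and ATF family, primary granule, secondary granule, and tertiary granule and secretory vesicle proteins, mature receptors and adhesion molecules, NADPH oxidase, anti-apoptotic and pro-apoptotic genes, cell cycle, myeloid transcription factors, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, immediate early and heat shock genes, integrated stress and unfolded protein response, histone acetyltransferases and deacetylases, extracellular trap and protease control genes, glycolysis, oxidative phosphorylation and ribosomal proteins. Markers of other cells that a sort might hold were erythroid, B cell, T and NK cell, monocyte and macrophage, dendritic cell, eosinophil, basophil and mast cell, osteoclast, megakaryocyte and platelet, stem and progenitor, and stromal and endothelial markers, with Y-linked genes and Xist as a label check. For each list with at least 5 passing members, the median difference was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. A list stood apart where its percentile was under 2.5 or over 97.5. This percentile describes the 2 arrays and is not a test between genotypes.

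The rule for named genes, also set before the data were examined, took Jdp2 and Atf3, the 12 highest and 12 lowest differences among passing genes without predicted or unnamed transcripts, up to 4 members of each list with the largest absolute difference, any AP-1 or ATF member, Xist and the Y-linked genes. Genes outside this rule, which include all members named from the lists added later, were chosen after their values were seen.

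The procedure was tested on simulated arrays, in which the real differences were shuffled among probe sets of like level and known shifts were added. With 11200 simulated genes, 90.0% of genes shifted by 1.5 in either direction and 100% of genes shifted by 3 passed the size rule, as did 4.8% of unshifted genes. Unshifted genes carried the shuffled real differences, so the 4.8% restates the share past 2-fold in the data and is no error rate. All probe sets of a shifted gene moved alike, which real genes need not do. Among 200 unshifted lists of 15 genes, 4.0% fell above and 2.0% below the central range, and 99.0% of lists shifted by 0.5 fell above it.

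Alternatives chosen before the data were examined were no level filter, a filter at the 75th percentile, a filter on both values, centring on array medians, quantile normalisation, removal of a loess trend on level (span 0.3), the mean of all probe sets of a gene, probe sets without the maker's marks for shared targets, the size rule on every probe set, size rules of 1.5-fold and 3-fold, and lists without shared members. A further 4 gene lists and a count without monocyte, primary granule and cell cycle genes were added after the data had been seen. Leaving out a replicate was not possible with 1 array per group. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.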

Results

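Gene expression was profiled in neutrophils, the phagocytes that are among the first cells to reach infected tissue, from the bone marrow of mice labelled Jdp2 knockout and of mice labelled wild type. Jdp2 (Jun dimerization protein 2) is a leucine-zipper protein of the AP-1 and ATF group that is known mainly as a repressor of transcription. The cells had been sorted by flow cytometry for surface CD11b and Ly6G with little Ly6C, and their RNA was hybridised to Affymetrix arrays. Each genotype was represented by 1 array, 2 in all, so there were no replicates, no spread between mice could be estimated, and no difference has a p-value. The number of arrays limits the precision of every value. The comparison asks which transcripts differ between neutrophils of the 2 labelled genotypes. Values are log2 signals, and differences are the array labelled knockout minus the array labelled wild type.

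The 2 arrays were similar in overall signal. Their medians over 45037 probe sets were 5.66 for the knockout label and 5.65 for the wild-type label, and the correlation across probe sets, which are not independent replicates, was 0.983. Signal ratios between the ends of control transcripts, which track RNA integrity, were close on both arrays. For Actb the 3′ probe set exceeded the 5′ probe set by 0.39 on the array labelled knockout and by 0.38 on the other, and for Gapdh by 0.64 and 0.63. The 18 hybridisation spike-in probe sets differed by a median of 0.03 in absolute value and by 0.11 at most.

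Jdp2 itself was not lower in the array labelled knockout. Its stronger probe set (1450350_a_at) read 12.38 there and 11.997 in the array labelled wild type, a difference of 0.38, and on both arrays it lay above the 97th percentile of all probe sets. The second probe set (1424972_at) read 5.40 and 5.24, below the median of each array. Neither the deleted part of the gene nor the position of these probes is given in the sources used here, and a probe outside the deleted part would check nothing. The labels are therefore unchecked by the targeted gene, and every direction below refers to the arrays as labelled. Xist, the transcript of the inactive X chromosome, was high on both arrays at 12.11 and 12.04. All probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty read at most 3.48 on either array.

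Atf3, a stress-induced relative of Jdp2, was 2.27-fold higher in the array labelled knockout (9.66 against 8.48, difference 1.18, probe set 1449363_at). Atf5 differed the other way, by -1.42, reading 4.57 against 5.99, which came to 1.25-fold with the value under the array median raised to that median. Among abundant members of the AP-1 and ATF family, Fos differed by 0.03, Jund by -0.02, Atf4 by -0.04, Jun by -0.08 and Mafg by -0.36. The following ranges cover all probe sets of a gene, including any below the level filter. They ran from -0.02 to 0.83 for Jund, from -0.46 to 0.10 for Atf4 and from -0.67 to -0.08 for Jun. Smaller differences were seen for Maf (0.74), Fosl1 (0.72), Maff (0.70), Batf (0.44), Junb (-0.46), Atf7 (-0.59) and Atf6b (-0.71). Probe sets of Atf7, on the same basis, ran from -0.59 to 1.11. Passing probe sets of Maf ran from 0.02 to 0.74. Fosl1 came to 1.08-fold with its lower value raised to the array median. Over the 24 family members that passed the level filter the median difference was -0.02, inside the range of matched random lists (percentile 62.3), and it changed sign when the arrays were centred on their medians (0.03).

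Across the transcriptome, 342 of 11168 genes were at least 2-fold higher in the array labelled knockout (3.06%) and 260 were at least 2-fold lower (2.33%). The highest were led by genes for the enzymes stored in primary granules, which neutrophils make at the promyelocyte stage. Mpo, encoding myeloperoxidase, read 11.02 against 5.93, a 34.0-fold difference, and Elane, encoding neutrophil elastase, read 9.36 against 5.75, a 12.3-fold difference. Ctsg, encoding cathepsin G, read 8.38 against 4.02, and Prtn3, encoding proteinase 3, read 7.26 against 4.41. Since the lower values of Ctsg and Prtn3 lay under the array median, their differences came to 6.64-fold and 3.06-fold with that value raised to the median. The probe sets of these 4 genes, in that order, were 1415960_at, 1422928_at, 1419594_at and 1419669_at. Of the 8 members of the primary granule list that passed the filter, 6 were at least 2-fold higher. The list's median difference was 1.95, and its percentile among 10000 matched random lists was 100. The other members, named after their values were seen, were Ctsc (1.05), Ms4a3 (1.04), Srgn (0.21) and Clec11a (-0.65). Ctsc encodes the protease that activates neutrophil elastase, cathepsin G and proteinase 3. Ms4a3 encodes a membrane protein and Clec11a a secreted growth factor, so neither is a gene for a granule enzyme. Another probe set of Ctsc pointed the other way, at -0.61.

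**Figure D1:**
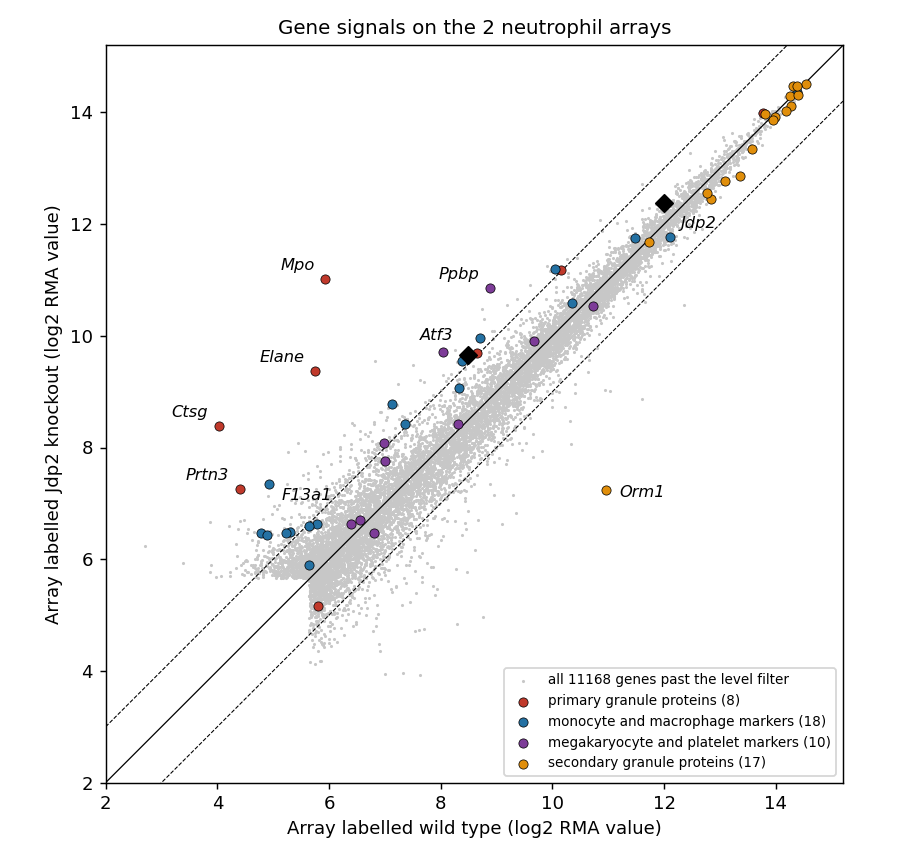
Each point is a gene that passed the level filter, with its log2 signal on the array labelled wild type on the horizontal axis and on the array labelled knockout on the vertical axis; the solid line marks equal signal, the dashed lines a 2-fold difference, colours the members of 4 gene lists, and black diamonds Jdp2 and Atf3. Mpo (11.02 against 5.93) lies farthest above the line, Orm1 (7.24 against 10.96) far below it, and Jdp2 (12.38 against 11.997) close to it.

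Markers of monocytes and macrophages were higher beside the primary granule genes. Of 18 such genes, 10 were at least 2-fold higher in the array labelled knockout, 16 had a difference above 0, and the list's median was 1.11 (percentile 100). F13a1, encoding the A chain of coagulation factor XIII, differed by 2.43 and Ms4a6c by 1.69. The mannose receptor gene Mrc1 differed by 1.64 and the complement gene C1qa by 1.54. With the lower value raised to the array median, F13a1 came to 3.25-fold, Ms4a6c to 1.76-fold and C1qa to 1.71-fold. Ms4a6c was at 0.92 with the mean of all its probe sets. Platelet genes were higher too as a list, with a median of 0.24 over 10 genes (percentile 97.8). The list was led by the chemokine genes Ppbp (1.97) and Pf4 (1.66) and the glycoprotein genes Gp1bb (1.09) and Gp9 (0.76). Of the 10 genes, 3 were at least 2-fold higher, and 2 lay below 0. These 2 were the integrin genes Itga2b (-0.34), named after its value was seen, and Itgb3 (-0.20). After quantile or loess normalisation the platelet list lay inside the random range, at percentiles 97.3 and 97.4. Without members of other lists it lay inside that range too, at percentile 96.5.

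Other cell types did not stand apart as lists. The median difference was -0.23 for erythroid markers (6 genes, percentile 9.12), 0.01 for B cell markers (8 genes, percentile 59.6), 0.28 for T and NK cell markers (6 genes, percentile 92.5) and 0.07 for dendritic cell markers (10 genes, percentile 71.5). It was -0.20 for osteoclast markers (7 genes, percentile 6.16), -0.13 for stem and progenitor markers (11 genes, percentile 20.7) and 0.00 for stromal and endothelial markers (8 genes, percentile 54.7). Averaging all probe sets of a gene put the B cell and dendritic cell lists outside that range, at medians of 0.61 and 0.35. Single members moved apart within these lists: Igll1 differed by 1.15 and Ighm by -0.93 among B cell genes, and Cd74 and H2-Eb1, of class II antigen presentation, by 1.09 and 0.97. H2-Ab1 differed by 1.04, but by 0.38 without shared probe sets, and the 3 passing probe sets of H2-Aa ran from -0.76 to 1.36. Cd48 (1.98), Mecom (1.34), Kit (-0.82) and Erg (-0.44) were the largest among progenitor genes, Col1a2 (1.51), Fabp4 (1.17), Col1a1 (-0.74) and Sparc (-0.42) among stromal genes, Nkg7 (0.70) and Cd8a (-0.66) among T and NK cell genes, and Car2 (-1.29) among erythroid and osteoclast genes. Averaging all probe sets of a gene brought Mecom to 0.61, Col1a2 to 0.57, Fabp4 to 0.59, Igll1 to 0.61, Ighm to -0.29, Kit to -0.38, Col1a1 to -0.50, Sparc to -0.14 and Cd8a to -0.16. Only 4 eosinophil, basophil and mast cell genes passed the filter, with a median of 0.25 and Ccr3 (1.13) at the top, which came to 1.19-fold with its lower value raised to the array median.

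The later granule programme did not stand apart. Secondary granule genes, among the most abundant transcripts of these cells, had a median difference of -0.08 (17 genes, percentile 5.83), and 16 of them lay within 2-fold. Many of these probe sets read near the top of the scale, where differences can be compressed. Camp read 14.51 and 14.54, and S100a8, a list member that encodes a cytosolic protein, read 14.47 and 14.30. Both were named after their values were seen, and the array maxima were 14.56 and 14.54. The exception was Orm1, encoding an acute-phase glycoprotein, which was 13.2-fold lower in the array labelled knockout (7.24 against 10.96, probe set 1451054_at). Chil1 differed by -0.49, Olfm4 by -0.39 and Itgb2l by -0.33. The secondary granule list lay outside the random range after quantile or loess normalisation, at a median of -0.13 under both. Tertiary granule and secretory vesicle genes had a median of -0.09 (9 genes, percentile 12.6), with Itgam at -0.43. Receptors and adhesion molecules of mature neutrophils had a median of 0.05 (24 genes, percentile 92.9), with Cd14 at -0.79 and Clec4e at 0.49. All 9 genes listed for the NADPH oxidase, which makes the oxidative burst, and for proteins that act with it had a difference below 0. Among them were Hvcn1, encoding a proton channel (-0.35), Ncf1 (-0.23) and Cybb (-0.22). The median of the 9 genes, -0.13, stayed inside the random range (percentile 4.94), and lay outside it after loess (-0.16). Genes of extracellular traps and protease control had a median of 0.02 (10 genes, percentile 66.2), with Cst7, encoding cystatin F, at 2.55. Cst7 read 5.92 against 3.38, which came to 1.21-fold with the lower value raised to the array median.

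Genes of DNA replication and division were slightly higher in the array labelled knockout, where monocyte and macrophage markers (median 1.11) and primary granule genes (median 1.95) were higher too. Of 38 cell cycle genes, 31 had a difference above 0 and none reached 2-fold, with a median of 0.29 (percentile 100). The helicase subunits Mcm3 (0.93) and Mcm6 (0.75), thymidylate synthase Tyms (0.64) and cyclin E2 Ccne2 (0.63) led the list. Averaging all probe sets of a gene brought Mcm3 to 0.70, Mcm6 to 0.43 and Tyms to 0.09. Ribosomal protein genes were higher in 16 of 17 cases, with a median of 0.23 (percentile 100) and the largest difference for Rpl22 (0.48). Glycolysis genes were lower in 13 of 16 cases, with a median of -0.21 (percentile 0.11). Lactate dehydrogenase A, Ldha, differed by -0.68, hexokinase 2, Hk2, by -0.50, and Pfkfb4 by -0.34. Pfkm, a phosphofructokinase subunit, differed by -1.14 at weak signal (4.55 against 5.69), which came to 1.02-fold with the lower value raised to the array median. Oxidative phosphorylation genes had a median of -0.08 (22 genes, percentile 18.5), with Ndufv1 at -0.55.

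**Figure D2:**
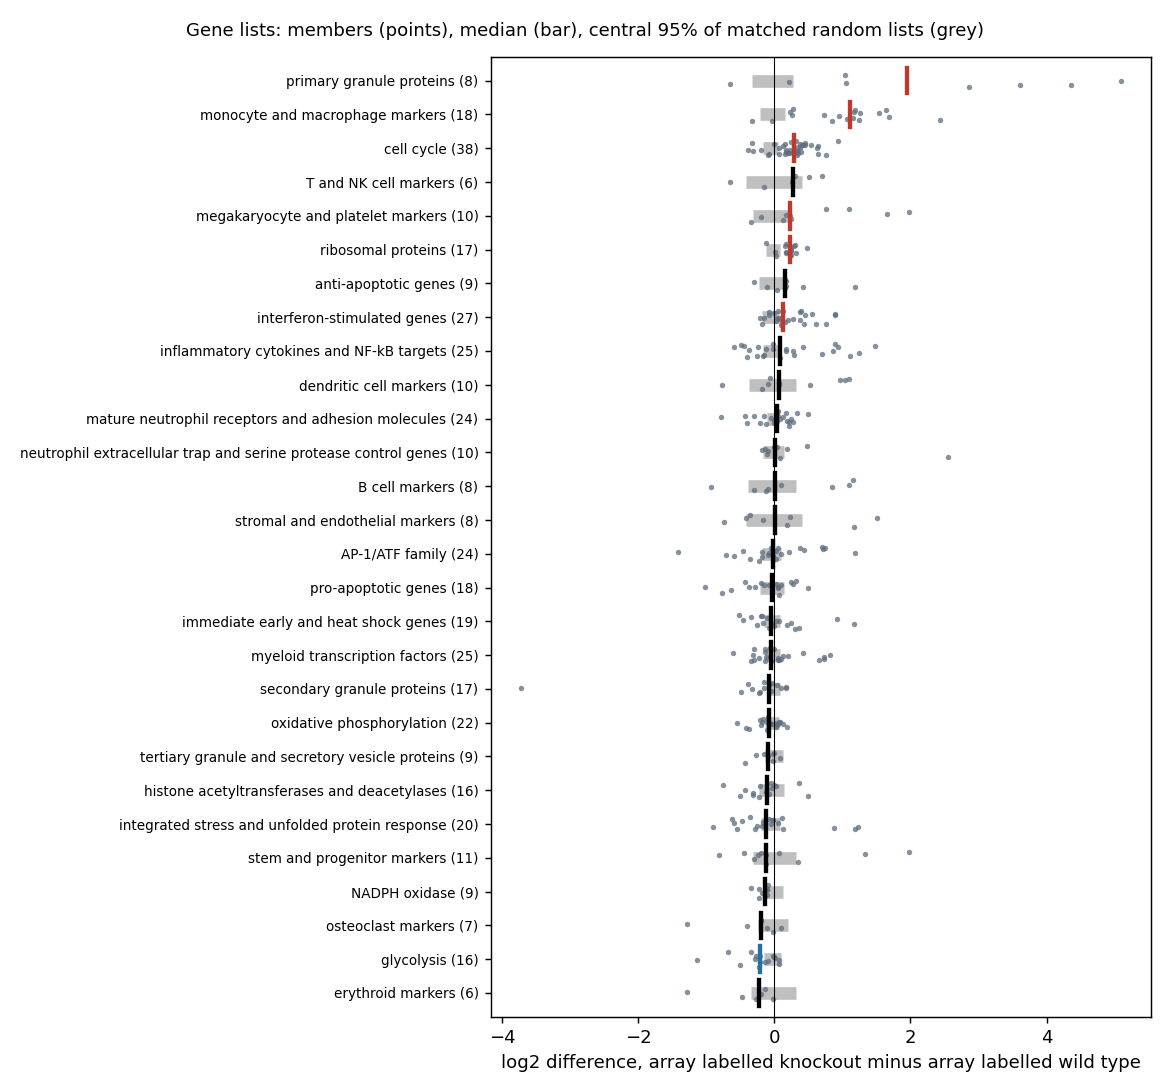
Each row is a gene list, with the number of genes that passed the filter in brackets; points are log2 differences of single genes (array labelled knockout minus array labelled wild type), vertical bars are list medians, red where higher, blue where lower and black where not apart from matched random lists, and grey bands span the central 95% of 10000 such lists. The primary granule median (1.95) and the monocyte and macrophage median (1.11) lie farthest to the right of their bands.

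Interferon-stimulated genes were slightly higher in the array labelled knockout, with a median of 0.13 over 27 genes (percentile 99.7) and 21 of them above 0. Monocyte and macrophage markers, with a median of 1.11, were higher in the same array, beside these genes and the chemokine genes below. The interferon-inducible GTPase genes Ifi47 and Gbp2 differed by 0.89 each, Ifit1 by 0.75 and Xaf1 by 0.61. Gbp2b, of the same GTPase family and in none of the lists, differed by -3.69, which came to 3.88-fold with its lower value raised to the array median. Inflammatory cytokines and NF-kB targets had a median of 0.08 (25 genes, percentile 96.7), and 3 chemokine genes passed 2-fold: Ccl9 (1.48), Ccl4 (1.24) and Cxcl2 (1.11). After shared probe sets were left out, their median was 0.12 and lay outside the random range. Anti-apoptotic genes had a median of 0.15 (9 genes, percentile 95), with Bcl2 at 1.19, which came to 0.20 without shared probe sets and to 1.27-fold with its lower value raised to the array median. Pro-apoptotic genes had a median of -0.03 (18 genes, percentile 51.9), with Bad at -1.02 (-0.43 over all probe sets, another passing probe set at 0.16). This median was above 0 under each of the 3 other scalings (0.01, 0.01 and 0.03), and with the mean of all probe sets it was -0.25 and lay outside the random range (percentile 2.41).

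The remaining regulator and stress lists did not stand apart. Myeloid transcription factors had a median of -0.05 (25 genes, percentile 33.3), with Id2 (0.81), Klf4 (0.74), Egr2 (0.72) and Irf4 (0.66) as the largest differences. Id2 had a passing probe set at -0.36, and the mean over all probe sets was 0.51 for Id2 and 0.10 for Irf4. Histone acetyltransferases and deacetylases had a median of -0.11 (16 genes, percentile 23.2), with Hdac10 at -0.76 and Hdac2 at -0.51, although the passing probe sets of Hdac2 ran from -0.82 to 0.39. Immediate early and heat shock genes had a median of -0.04 (19 genes, percentile 41.0), with Hsph1 at 1.17 (0.48 over all probe sets) and Hspa1b at 0.93 (0.67). Genes of the integrated stress and unfolded protein responses had a median of -0.12 (20 genes, percentile 21.6), with Ddit4 at 1.22, Asns at -0.90 and Phgdh at 0.87, although the 4 passing probe sets of Phgdh ran from -0.10 to 1.35. The medians of the immediate early, trap, B cell and stromal lists, all close to 0, changed sign under at least 1 other scaling. In all, 6 of the 28 lists with a percentile stood apart as higher and 1 as lower. For lists of independently drawn genes, 1.4 would be expected outside the central 95%. Members of a real list can vary together and some lists share members, so this comparison measures no excess over chance.

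Beyond the lists, the highest differences were seen for Fam167a (3.54), the urea transporter gene Slc14a1 (2.79), the ribonuclease gene Rnase6 (2.73), Rgs1 (2.66), encoding a regulator of G-protein signalling, Rbpms (2.63) and Timm9 (2.38). Rnase6 read 9.55 against 6.82, while Fam167a read 6.24 against 2.71, which came to 1.51-fold with the lower value raised to the array median. The lowest differences, apart from Orm1 and Gbp2b, were those of Bend4 (-3.80), Cmah (-3.45), Mfap3l (-3.36), Tmem45a2 (-3.05), the kinase gene Styk1 (-2.94), Tmem159 (-2.89), Niban3 (-2.84), the formin gene Fmnl2 (-2.73), the endothelial lipase gene Lipg (-2.69) and Junos (-2.55). Fmnl2 was the most abundant of these, at 8.87 against 11.60. With the lower value raised to the array median, the differences came to 8.54-fold for Bend4, 6.14-fold for Cmah, 3.16-fold for Mfap3l, 2.51-fold for Tmem45a2, 4.08-fold for Styk1, 3.87-fold for Tmem159, 3.68-fold for Niban3 and 2.37-fold for Junos. Junos is antisense to Jun, which differed by -0.08, and its signal is uncertain because the strand of its probes was not checked. In 9 of the 12 highest and 9 of the 12 lowest genes, the lower value lay under the array median. Other probe sets of some genes did not show the same size: Rbpms had another passing probe set at 0.36, Bend4 one at -1.08, and the 4 passing probe sets of Cmah ran from -3.45 to 0.15. Lipg was at -3.74 without shared probe sets and at -2.28 with the mean of all its probe sets. For Slc14a1, Timm9, Mfap3l and Tmem159, other probe sets, all below the level filter, reached 0.20, 0.09, 0.61 and 0.05. Averaging all probe sets of a gene also brought Maf to 0.47 and Xaf1 to 0.03. With the lower value raised to the array median, Slc14a1 came to 2.03-fold, Rgs1 to 4.83-fold, Rbpms to 5.36-fold and Timm9 to 1.92-fold.

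The only error estimate the design gives is technical. Among 4867 genes with several passing probe sets, the SD of the difference over a gene's probe sets had a median of 0.22 and a 90th percentile of 0.58. Of the 602 genes past 2-fold, 152 had other passing probe sets: in 47 all of these were past 2-fold in the same direction, in 70 at least 1 was under 0.5 in that direction, and in 31 at least 1 pointed the other way. Weak signal carried most of the counts, since 302 of the 342 higher genes and 213 of the 260 lower genes lay below 8.18, the median level of genes that passed the filter.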

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

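The tests of the signal-level trend, of other probe sets of a gene and of exchanged labels, and the look at the deleted part, were chosen after the results they address had been seen; the gene lists and neighbour tests below were written before their own results, but after a first look at the data.

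Signal outside the named genes also differed. Of 3872 probe sets with no gene in the annotation that passed the level filter, 194 were at least 2-fold higher in the array labelled knockout, by up to 2.57, and 127 were at least 2-fold lower. Of 613 passing probe sets with several genes, 16 were at least 2-fold higher, by up to 3.12, and 6 were at least 2-fold lower. Both are listed here because these probe sets entered no comparison between genes.

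Primary granule genes were higher in the array labelled knockout (median 1.95), together with monocyte and macrophage markers (median 1.11), a direction that rests on labels that Jdp2 does not check. Removing a trend of the difference on signal level by loess left the median at 1.99. The sorted values of the 2 arrays differed by at most 0.117, so this step could hardly have removed such a difference and decides little. Monocyte-lineage cells in the sort may contribute, but this is not settled. A second list of 19 passing monocyte genes, sharing 0 genes with the fixed lists, had a median of 0.68 (percentile 100). Its bootstrap interval over genes, 0.05 to 0.86, spans its upper random limit of 0.15. The list was led by Ctss, named after its value was seen, at 11.24 against 9.91. It holds no primary granule gene, so it shows again that monocyte genes were higher, not why primary granule genes were. Of the 19 genes, 16 had wild-type signal at or above the median. The sort was for Ly6G with low Ly6C, markers whose own transcripts were not analysed by name here. Early neutrophil precursors stay open and cannot be told apart from no change, since their list of 22 passing genes, 7 of whose 26 members are in the fixed lists, had a median of 0.08 (percentile 96.5) and an interval of -0.02 to 0.30 that spans the upper random limit of 0.09. A difference in maturation tied to the Jdp2 genotype also stays open, as untested with 1 array per group, and none of these tests shows which cells carried Mpo.

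The 602 genes past 2-fold were measured in mice of mixed strain background, where differences can come from strain variants linked to or apart from Jdp2, and from noise. Noise of single probe sets as the whole source is argued against for the 152 of these genes that had other passing probe sets. Of 210 such probe sets, 176, or 83.8%, pointed the same way, although with a median of 0.68. The exact binomial interval, 78.1 to 88.5, counts probe sets of 1 gene as independent, which they are not. The other genes past 2-fold had no such check. The 100 measured genes on either side of Jdp2 held 12 genes past 2-fold, against a median of 11 over 7138 windows (percentile 64.1). This did not exceed the 95th percentile of 16, the limit written before the count was seen. Whether a segment around Jdp2 holds an excess still stays open, since the exact Poisson interval of the count, 6.20 to 20.96, spans that limit. Strain segments elsewhere may add a part: 47 pairs of neighbouring genes were both past 2-fold, against a median of 32 in shuffles (percentile 99.6), an excess of 15. Without pairs whose names share 3 letters there were 43 against 31 (percentile 98.4). That name rule leaves in co-expressed neighbours such as Ppbp with Pf4 and Prtn3 with Elane. The pairs therefore cannot tell strain segments from co-expression. The genotype stays open as untested.

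Jdp2 signal was not lower in the array labelled knockout (12.38 against 11.997). Exchanged labels cannot be told apart from correct ones by this gene, since the difference of 0.38 lies within 2-fold and the probe set decides nothing if it lies outside the deleted part. That second explanation, a probe set outside the deleted part, may apply: the signal lay above the median on 2 of 2 arrays, and no source used here gives the deleted part or the probe positions. No biological explanation was tested.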

How the results depend on the processing

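The 7 lists that stood apart kept their direction under all alternatives run. Among alternative values of the lists, 203 kept their side of the random range, 10 moved outside it and 3 moved inside it. Among named genes, 605 values moved by less than the technical spread and 42 by more, most of them when all probe sets of a gene were averaged. The rest of the 42 came from leaving out shared probe sets. The other scalings could hardly move a value, since the sorted values of the arrays differed by at most 0.117. Averaging leaves a gene with a single probe set unchanged. The 605 is therefore no measure of stability. The counts of genes higher and lower in the array labelled knockout (342 and 260) were 110 and 87 with the filter at the 75th percentile, 184 and 145 with both values above the median, 183 and 171 with the mean of all probe sets (172 and 162 of these shared with the main counts), and 157 and 147 when every probe set had to pass. They were 948 and 989 at 1.5-fold and 71 and 68 at 3-fold. Apart from the mean of all probe sets, the direction of these shifts follows from the stricter or looser rules themselves. The size of the drop under the stricter filters also reflects weak signal. Of the 602 genes past 2-fold, 515 lay below the median level of genes that passed the filter. The other scalings, no filter and probe sets without shared targets left the counts within 1.5 times, as did leaving out monocyte, primary granule and cell cycle genes, a count of 326 chosen after seeing the data. Technical spread was 0.14 with the filter at the 75th percentile, and the Jdp2 difference was 0.16 for the second probe set.

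Of the lists, secondary granule genes moved outside the random range after quantile normalisation (-0.13), loess (-0.13) and without shared probe sets (-0.11), and NADPH oxidase genes after loess (-0.16). The mean of all probe sets did so for mature receptors (0.058), pro-apoptotic genes (-0.25), inflammatory genes (0.089), B cell markers (0.61) and dendritic cell markers (0.35), and leaving out shared probe sets for inflammatory genes (0.12). Megakaryocyte and platelet markers moved inside it after quantile normalisation (0.27), loess (0.28) and without members of other lists (0.25). The cause was not tested. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. Weak signal is a further limit: in 273 of the 602 genes past 2-fold the lower value lay under its array's median.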

Other observations

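The glucocorticoid and clock lists below were written after a first look at the data, before their own results were seen, and directions again follow the labels. The members named from them were chosen after their values were seen.

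Per1, a gene of the circadian clock that glucocorticoids also induce, was higher in the array labelled knockout (9.14 against 7.24, difference 1.90) and prompted this look after its value was seen. Other glucocorticoid-induced genes may share that direction, but this is not settled. With Per1 left out, 12 of 17 passing genes had a difference above 0, with a median of 0.24 (percentile 99.9 among matched random lists). The bootstrap interval over genes, -0.02 to 0.91, spans both 0 and the upper random limit of 0.13. Ddit4 (1.22), the metallothionein genes Mt1 (1.29) and Mt2 (1.03), the scavenger receptor gene Cd163 (1.11) and Klf9 (0.91) led the list, with the lower values of Mt1 and Mt2 under the array median, while Fkbp5 differed by 0.24, Tsc22d3 by 0.34 and Errfi1 by -0.70. Of its 19 members 4 are in the fixed lists, Per1 is also in the clock list, and Cd163 is also a macrophage gene. The remaining clock genes went both ways, with Nr1d1 at 0.85 and Per2 at -1.25, and a median of -0.15 over 12 genes (percentile 18.2, interval -0.31 to 0.30), which decides nothing on a shift of the clock.

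The 12 genes past 2-fold near Jdp2, named after their values were seen, included Timm9 (2.38) and Tc2n (2.28) as the highest and Acot1 (-1.97) and Slc38a6 (-1.88) as the lowest. The hemoglobin gene Hba-a2, also chosen after its values were seen, read 13.20 and 13.21 on the 2 arrays of sorted neutrophils.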
